A study of Macaca mulatta with 48 samples.

How the data were processed

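Gene expression was measured on 48 Affymetrix arrays (chip type HG_U95Av2 per the file headers), which carry 12625 human probe sets, hybridised with total RNA from post-mortem brain tissue of 12 rhesus macaques. Per the labels, 6 animals were uninfected controls (298, 331, 332, 357, 392 and 393) and 6 were infected with SIV (289, 301, 321, 323, 328 and 330). Animals are written below as group and number, control-331 or SIV-289 for example. The deposited values are 1 intensity per probe set and array on a linear scale. How the authors summarised probes into these intensities, and with which software, is not given in the sources used here. The 2%-trimmed means of the arrays lay between 250.07 and 250.13 and the medians between 89.4 and 137.2, so the deposited scale was kept with no further normalization. The experiment records of the instrument software are of the kind other: per the file headers they hold chip lot, fluidics protocol and sample description for each array and no expression values. They were used for lot (6 lots), protocol version (30 arrays under version 3 and 18 under version 4) and the recorded sample names only.

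Before the data were examined, the comparisons, tests, filters, gene lists, the rule for named genes and most alternatives had been written down. Intensities were floored at the 20th percentile of all values (32.9, with 12.2% to 27.2% of an array's values at the floor) and taken to log2. The 67 control probe sets of the manufacturer were removed, leaving 12558; of these 10943 carried 1 gene symbol, 545 several and 1070 none in the annotation used here. Probe sets without a symbol were tested and counted but are not named; some genes of the fixed lists are for this reason not reported here. For each fit a probe set was kept if it lay above the median of its own array in at least as many animals as the smaller group held. The frontal lobe repeat arrays of an animal were averaged on the log2 scale, so n counts animals.

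SIV and control animals were compared in each region with limma 3.58.1 under R 4.3.3 (linear fit and moderated two-sided test), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A single limma fit of 8 groups (infection by region) over 36 samples, with the animal as a random block (consensus correlation 0.0413) and 9696 probe sets, gave the average SIV effect over regions, the difference of each region's SIV effect from that in frontal lobe, and the contrasts between regions in control animals. The numbers in the labels name animals, so the same number in several regions marks tissue of 1 animal and pairs regions; control and SIV animals share no number. Correlations of the deviations of an animal's samples from their group means, over 500 probe sets, were highest with the animal's own other regions in 23 of 34 samples. The midbrain sample of SIV-289, whose record names another animal, was tested apart from these and did not match its own number best. Apart from control-331, each animal's arrays fell in a single period of array processing, early or late. A match may therefore also come from the period.

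The 22 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. Each gene was represented by the probe set with the highest mean log2 value, which gave 8226 genes, and lists of fewer than 3 measured genes were not tested. Members of a list were adjusted over all tested probe sets and, beside that, over the list alone. The lists were interferon-stimulated genes, MHC class I and antigen processing, MHC class II, macrophage and microglia, chemokines with cytokines and adhesion molecules, complement, T and NK lymphocyte, B lymphocyte and plasma cell, red blood cell, astrocyte, oligodendrocyte and myelin, neuronal, glutamatergic synapse, GABAergic neuron and peptide, immediate early, vascular and connective tissue, metallothionein and heat shock, hypoxia and glycolysis, mitochondrial electron transport, cerebellar neuron, midbrain monoaminergic and forebrain cortex genes. Brain tissue is a mixture of cells, so marker lists are not shares of cells.

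Genes named in the report followed a fixed rule. Per SIV comparison they were those past the threshold with the largest absolute change and a single symbol: 14 higher and 10 lower in frontal lobe and over all regions, 8 and 6 in midbrain and cerebellum, 5 and 5 in occipital lobe. Where fewer passed, those with the smallest p were given as values that did not pass. For contrasts between regions the limit was 8 in each direction, for differences of the SIV effect 6. Up to 4 members of each list by smallest p were added, with GFAP, CD163, CD14, CD68, B2M, MX1, CCL2, SPP1, MBP and SNAP25 always considered. Not every gene the rule allows is printed.

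Ratios of 3' to 5' control probe sets of GAPDH and beta-actin were compared with exact permutation tests over animals, two-sided. Agreement between regions was compared with all 70 exchanges of animals that keep the group sizes of every region. The number of calls was also taken under up to 100 other groupings of the samples with a fixed seed. Arrays were placed in an early (28 arrays) or late (20 arrays) period from the code that opens each title, and the recorded hybridisation days matched these codes for all 48 arrays. Controls and SIV animals in the early and late period numbered 4 and 2 against 3 and 3 in frontal lobe, 3 and 1 against 1 and 3 in midbrain, 4 and 1 against 2 and 3 in cerebellum, and 1 and 1 against 3 and 1 in occipital lobe. Period was not in the fits reported and was added in alternatives.

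The pipeline was tested on simulated data of the same layout. Of probe sets given a log2 change of 1, 51 of 93 (54.8%) were recovered in frontal lobe, 32 of 96 (33.3%) in midbrain, 17 of 94 (18.1%) in cerebellum, 0 of 92 in occipital lobe and 83 of 96 (86.5%) over all regions. For a log2 change of 2 these were 84 of 89 (94.4%), 64 of 85 (75.3%), 57 of 80 (71.2%), 0 of 92 and 94 of 94 (100%). False calls numbered 2, 10, 6, 0 and 9. A simulated list moved by 0.5 was recovered, and 1 of 20 lists that had not been moved was called. Simulated genes varied independently of each other, so this does not measure how often lists of correlated genes are called falsely. The precision of every comparison was limited by the number of arrays, and most in occipital lobe with 2 controls.

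Alternatives tried were quantile normalization, floors at the 10th and 40th percentile, no filter and a filter at the 75th percentile, period as a block or alone, ratio covariates, trend and robust variance, array weights, single or all repeat arrays, other block settings, other list settings and leaving out each animal. Leaving out the 7 samples whose log2 ratios were both above 1, using the beta-actin ratio as a covariate in midbrain, and leaving out animals in the difference and region contrasts were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Raw scan images and probe-level data were not used here.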

Results

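Messenger RNA levels were measured in post-mortem brain tissue of 12 rhesus macaques, 6 infected with simian immunodeficiency virus (SIV), a lentivirus that causes an AIDS-like disease in this species, and 6 uninfected controls. Each array was an Affymetrix GeneChip carrying human probe sets, so macaque transcripts were read through probes designed on human sequence. The 48 arrays covered frontal lobe in 6 control and 6 SIV animals, with a repeat array for every animal, midbrain in 4 and 4, cerebellum in 5 and 5, and occipital lobe in 2 and 4. The arrays were scaled to a common trimmed mean, between 250.07 and 250.13 intensity units, while their medians ran from 89.4 to 137.2. Changes below are on the log2 scale with the standard error (SE) of the fit, and n counts animals. Precision was limited by the number of arrays.

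Repeat arrays gave the spread between arrays of one animal; whether they share an RNA preparation is not given in the sources used here. Over 7601 probe sets, the 12 pairs of frontal lobe arrays from one animal had a median Pearson correlation of 0.876, from 0.804 to 0.933. The 120 pairs from different animals of one group had a median of 0.855, from 0.686 to 0.905, with a minimum of 0.818 without control-392. These correlations run across probe sets within a pair of arrays, and probe sets are not independent replicates. On the log2 scale the median SD between repeat arrays, taken from single arrays, was 0.463. Between animals of one group it was 0.455, taken from the average of each animal's repeat arrays. Averaging lowers the array error, so these SDs are on unlike bases and do not show that animals differ as little as repeats.

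RNA integrity was read from control probe sets placed at the 3' and 5' ends of the GAPDH and beta-actin transcripts, where a higher 3' to 5' ratio marks more degraded RNA. In frontal lobe the SIV minus control difference in the log2 ratio was -0.14 for GAPDH (two-sided exact permutation p = 0.602, n = 6 and 6) and -0.07 for beta-actin (exact p = 0.894). In midbrain beta-actin was higher in SIV animals, 2.12 ± 1.30 (SD, n = 4) against 0.60 ± 0.27 (n = 4), with an exact p = 0.0286, the smallest that 4 against 4 animals can give, and a Benjamini-Hochberg value of 0.229 over the 8 tests. GAPDH there differed by 0.88 (exact p = 0.171, n = 4 and 4). The differences in cerebellum were 0.06 for GAPDH and 0.33 for beta-actin (exact p = 0.937 and 0.548, n = 5 and 5). In occipital lobe GAPDH was lower in SIV animals by -1.10 (exact p = 0.0667, the smallest that 2 against 4 animals can give) and beta-actin differed by 0.35 (exact p = 0.600). Both log2 ratios lay above 1 in 7 samples. These were the frontal lobe of control-392, the occipital lobe and cerebellum of control-331, the midbrain of SIV-289 and SIV-301, and the cerebellum of SIV-323 and SIV-328.

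**Figure D1:**
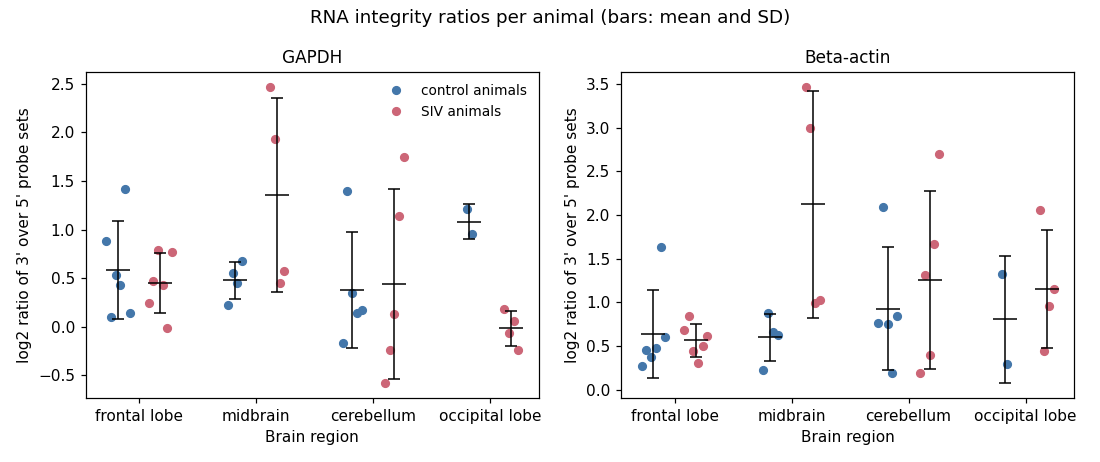
The log2 ratio of 3' over 5' control probe sets is plotted for each animal in each brain region, GAPDH on the left and beta-actin on the right, with bars for the mean and SD of each group. The SIV midbrain points average 2.12 for beta-actin against 0.60 in control midbrain.

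In frontal lobe, SIV infection came with a large rise of genes that interferon switches on. MX1, a GTPase that blocks virus replication, was 17.0-fold higher in SIV animals (log2 change 4.09 ± 0.38 SE, adjusted p = 1.15e-05, n = 6 and 6), with 2 controls at the intensity floor. IFI27 was 15.2-fold higher (3.92 ± 0.36, adjusted p = 9.49e-06) and IFIT1, which binds foreign RNA, 12.5-fold higher (3.64 ± 0.31, adjusted p = 6.79e-06). CD14, the lipopolysaccharide co-receptor of monocytes and macrophages, rose 5.32-fold (2.41 ± 0.20, adjusted p = 6.45e-06), and C1QB, a subunit of complement C1q made in brain by microglia and macrophages, rose 8.99-fold (3.17 ± 0.37, adjusted p = 1.28e-04). For each of these 5 genes all 6 SIV animals lay above every control animal.

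Of 6356 probe sets tested in frontal lobe, 86 passed an adjusted p of 0.05, 77 higher and 9 lower, and 819 had an unadjusted p under 0.05. The 71 called probe sets with a single gene symbol held 56 genes that rose and 7 that fell; 6 others carried several symbols and 9 none here. Of the 25 interferon-stimulated genes measured, 11 rose and 14 did not pass; adjusted over the list alone, 19 were higher and 1 lower. The list mean was 1.64 (camera adjusted p = 3.31e-27, and adjusted p = 0.00844 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose 9.56-fold (3.26 ± 0.40, adjusted p = 2.07e-04) and IFI44 7.84-fold (2.97 ± 0.27, adjusted p = 1.04e-05). Among 8 genes of MHC class I and antigen processing, 6 rose and 2 did not pass (7 adjusted over the list alone; list mean 1.62, adjusted p = 1.37e-16, adjusted p = 0.00844 with an estimated correlation). They included B2M, the class I light chain, at 5.57-fold (2.48 ± 0.36, adjusted p = 8.83e-04). The immunoproteasome subunit PSMB9 rose 5.12-fold (2.35 ± 0.31, adjusted p = 3.54e-04) and HLA-G 5.66-fold (2.50 ± 0.25, adjusted p = 2.12e-05). The HLA-G probe set is of the kind whose suffix marks a family of similar sequences, so its signal can come from other class I genes.

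The MHC class II list also rose in frontal lobe, with 2 of 8 genes higher and 6 not passing (6 higher adjusted over the list alone; mean 0.98, adjusted p = 1.19e-08, adjusted p = 0.0113 with an estimated correlation). CD74, the invariant chain, rose 4.59-fold (2.20 ± 0.27, adjusted p = 2.07e-04) and HLA-DMA, which helps load peptides, 4.18-fold (2.06 ± 0.24, adjusted p = 1.28e-04). Of 21 macrophage and microglia markers 6 rose and 15 did not pass (11 adjusted over the list alone; mean 1.03, adjusted p = 1.53e-15, adjusted p = 0.00844 with an estimated correlation). Among them were CD37 at 4.03-fold (2.01 ± 0.24, adjusted p = 1.72e-04) and LAPTM5 at 2.93-fold (1.55 ± 0.22, adjusted p = 7.15e-04). The scavenger receptor CD163 measured 1.64 ± 0.42 (adjusted p = 0.0755) and did not pass. In the complement list 2 of 5 genes rose, C2 and C1S, and 3 did not pass (3 adjusted over the list alone; mean 0.79, adjusted p = 1.09e-04, adjusted p = 0.0334 with an estimated correlation). Both calls sat near the threshold, each at an adjusted p = 0.0457, and were lost in 10 and 8 of the 12 refits that left out 1 animal. Of 12 chemokines, cytokines and adhesion molecules 1 rose, SPP1 (osteopontin) at 2.65-fold (1.40 ± 0.28, adjusted p = 0.0170), and 11 did not pass (2 adjusted over the list alone; mean 0.39, adjusted p = 0.00833, adjusted p = 0.0920 with an estimated correlation). SPP1 no longer passed without SIV-301 or SIV-323, with an adjusted p of up to 0.0573 over the refits.

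Vascular and connective tissue markers rose in 3 of 12 cases in frontal lobe and 9 did not pass (6 adjusted over the list alone; mean 0.57, adjusted p = 1.11e-04, adjusted p = 0.0579 with an estimated correlation). VWF, the endothelial clotting protein, rose 3.48-fold (1.80 ± 0.31, adjusted p = 0.00531) and fibronectin FN1 2.23-fold (1.16 ± 0.22, adjusted p = 0.0113). The third, PECAM1, an endothelial adhesion protein, lost its call (adjusted p = 0.0457) in 9 of 12 refits without 1 animal, and its change ran from 0.70 to 1.57 over the alternatives. TIMP1, an inhibitor of matrix metalloproteinases, rose 10.9-fold (3.44 ± 0.55, adjusted p = 0.00224). Of 20 astrocyte markers 1 rose, CHI3L1, a chitinase-like protein made by macrophages as well as astrocytes, at 4.05-fold (2.02 ± 0.36, adjusted p = 0.00652; 4 adjusted over the list alone; mean 0.33, adjusted p = 0.00578, adjusted p = 0.198 with an estimated correlation). GFAP, the astrocyte filament protein, measured 0.53 ± 0.23 (adjusted p = 0.342). No member of 3 lists that fell as groups passed on its own. The 25 neuronal markers averaged -0.21 (0 adjusted over the list alone; adjusted p = 0.00833, adjusted p = 0.411 with an estimated correlation). The 11 GABAergic neuron and peptide genes averaged -0.37 (0 adjusted over the list alone; adjusted p = 0.00176, adjusted p = 0.0201 with an estimated correlation). The 5 midbrain monoaminergic markers averaged -0.58 (adjusted p = 0.00780, adjusted p = 0.0533 with an estimated correlation; 2 lower adjusted over the list alone). Lower genes included NTRK3, the neurotrophin receptor TrkC, which fell by 1.07 (-1.07 ± 0.20, adjusted p = 0.0102), and ENSA, an inhibitor of a protein phosphatase, which fell by 0.91 (-0.91 ± 0.18, adjusted p = 0.0137). Both lost the call with the second array of each animal alone. The calls of the other 5 lower genes, CCDC9, PANK3, GCHFR, DNAJB5 and NR4A3, were each lost in 8 to 11 of 12 refits without 1 animal. With the period of array processing as a block 90 probe sets were called, with 47 among the early arrays alone and 0 among the late arrays alone, where limma gave no call with 2 control and 3 SIV animals.

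In midbrain genes of the interferon response also had the largest changes. MX1 was 33.7-fold higher in SIV animals (5.08 ± 0.44, adjusted p = 0.00129, n = 4 and 4; 3 controls at the floor), IFI27 16.5-fold (4.05 ± 0.41, adjusted p = 0.00259) and IFI44 11.9-fold (3.58 ± 0.33, adjusted p = 0.00129). TYMP, thymidine phosphorylase, was at the floor in all 4 controls and at least 16.7-fold higher in SIV midbrain (adjusted p = 0.00259). PSMB8, an immunoproteasome subunit, was likewise at least 14.9-fold higher (adjusted p = 0.00459), and GBP2, an interferon-induced GTPase, at least 9.68-fold higher (adjusted p = 0.00566). Over the alternatives, floors included, the log2 change ran from 4.03 to 5.71 for MX1, 2.77 to 4.87 for TYMP and 1.99 to 4.14 for GBP2, and was as low as 2.61 for PSMB8. CCL8, a chemokine that attracts monocytes, rose 6.32-fold (2.66 ± 0.35, adjusted p = 0.00566), from 1.68 to 3.20 over the alternatives. In all of these genes each of the 4 SIV animals lay above every control animal.

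Of 6436 probe sets tested in midbrain 86 were called, 68 higher and 18 lower, and 906 had an unadjusted p under 0.05. They held 53 genes that rose and 17 that fell; 7 called probe sets carried several symbols and 7 none here. Of 32 interferon-stimulated genes 16 rose and 16 did not pass (27 adjusted over the list alone; mean 2.07, adjusted p = 2.94e-33, adjusted p = 0.0567 with an estimated correlation). Of 10 genes of MHC class I and antigen processing 4 rose and 6 did not pass (10 adjusted over the list alone; mean 1.79, adjusted p = 4.18e-14, adjusted p = 0.0840 with an estimated correlation), with PSMB9 at 4.88-fold (2.29 ± 0.29, adjusted p = 0.00565). None of 10 MHC class II genes passed, although the list did (mean 0.84, adjusted p = 0.00147, adjusted p = 0.188 with an estimated correlation; 0 adjusted over the list alone, all 10 measured higher). Of 22 macrophage and microglia markers 2 rose and 20 did not pass (10 adjusted over the list alone; mean 0.94, adjusted p = 1.80e-09, adjusted p = 0.0744 with an estimated correlation). These were C1QB at 6.10-fold (2.61 ± 0.47, adjusted p = 0.0272) and CD68, a lysosomal protein of macrophages, at 4.42-fold (2.14 ± 0.41, adjusted p = 0.0377), with the calls lost in 5 and 7 of the 8 refits without 1 animal. CD163 measured 1.80 ± 0.42 (adjusted p = 0.0807).

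Of 16 chemokines, cytokines and adhesion molecules in midbrain 2 rose, CCL8 and CCL2, and 14 did not pass (2 adjusted over the list alone; mean 0.55, adjusted p = 0.00345, adjusted p = 0.0806 with an estimated correlation). CCL2, the main monocyte chemoattractant, rose 3.25-fold (1.70 ± 0.32, adjusted p = 0.0353), a call lost in 7 of 8 refits. In the complement list 1 of 5 genes rose, C2 (3 adjusted over the list alone; mean 0.80, adjusted p = 0.0187, adjusted p = 0.122 with an estimated correlation), a call lost in 5 of 8 refits without 1 animal and in 6 of 14 alternatives. Of 12 vascular markers 2 rose, VWF and COL4A1 (4 adjusted over the list alone; mean 0.49, adjusted p = 0.0132, adjusted p = 0.122 with an estimated correlation), and those calls were lost in 7 and 6 of 8 refits. The lists that fell were 14 oligodendrocyte and myelin genes (mean -0.37, adjusted p = 0.0194, adjusted p = 0.122 with an estimated correlation) and 25 neuronal markers (mean -0.37, adjusted p = 0.00373, adjusted p = 0.284 with an estimated correlation). Lower as well were 13 glutamatergic synapse genes (mean -0.62, adjusted p = 0.00731, adjusted p = 0.126 with an estimated correlation) and 23 mitochondrial electron transport genes (mean -0.22, adjusted p = 0.0472, adjusted p = 0.126 with an estimated correlation). No member of these 4 lists passed on its own; adjusted over the list alone, 1 oligodendrocyte and 2 glutamatergic genes were lower, and 0 of the other lists. The immediate early gene DUSP1, a phosphatase that switches off MAP kinases, fell by 1.59 (-1.59 ± 0.21, adjusted p = 0.00566). EPHA4, an ephrin receptor of axon guidance, fell by 2.15 (-2.15 ± 0.27, adjusted p = 0.00507). IL27RA, a cytokine receptor, fell by 2.22 (-2.22 ± 0.27, adjusted p = 0.00459) and MASP2, a protease of the lectin pathway of complement, fell by 2.35 (-2.35 ± 0.34, adjusted p = 0.00994). These 4 lower genes all lost the call without the samples of raised ratios and with the beta-actin ratio as a covariate. Over the alternatives their changes ran from -1.63 to -1.40 for DUSP1, -2.32 to -1.17 for EPHA4, -2.52 to -1.11 for IL27RA and -2.66 to -1.50 for MASP2. SIV midbrain was the group with the raised beta-actin ratio of 2.12. Without SIV-289 and SIV-301, whose ratios were raised, 37 probe sets were called, 35 with the beta-actin ratio as a covariate, and 51 with the GAPDH ratio. The count was 68 with array period as a block and 0 by limma within either period alone, where 1 group held a single animal and a 0 says nothing on period. Leaving out control-331, control-332, SIV-289 or SIV-328 gave 48, 44, 48 or 57.

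In cerebellum 12 probe sets passed, all higher in SIV animals, from 6423 tested with 268 at an unadjusted p under 0.05. They held 8 genes, with 1 further probe set of several symbols and 1 of none here. IFI27 was 13.1-fold higher (3.71 ± 0.44, adjusted p = 0.00171, n = 5 and 5), IFIT1 12.1-fold (3.60 ± 0.48, adjusted p = 0.00458) and IFI44 9.05-fold (3.18 ± 0.44, adjusted p = 0.00458). CHI3L1 was 8.10-fold higher (3.02 ± 0.30, adjusted p = 7.58e-04), with 4 of 5 controls at the floor and a change of 1.74 to 3.54 over the alternatives. B2M was 7.89-fold higher (2.98 ± 0.41, adjusted p = 0.00458) and PSMB9 6.03-fold (2.59 ± 0.35, adjusted p = 0.00458). In each of these 6 genes all 5 SIV animals lay above every control animal. ISG15 at 4.12-fold (2.04 ± 0.33, adjusted p = 0.0191) and the secreted glycoprotein LGALS3BP at 4.36-fold (2.12 ± 0.35, adjusted p = 0.0234) also passed, but lost the call in 5 and 6 of 10 refits without 1 animal.

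Of 22 interferon-stimulated genes in cerebellum 5 rose and 17 did not pass (12 adjusted over the list alone; mean 1.39, adjusted p = 1.16e-24, adjusted p = 0.00173 with an estimated correlation). Of 9 MHC class I genes 2 rose and 7 did not pass (5 adjusted over the list alone; mean 1.32, adjusted p = 1.92e-14, adjusted p = 0.0166 with an estimated correlation). Vascular markers rose as a list with none of 9 passing (2 adjusted over the list alone; mean 0.53, adjusted p = 0.00275, adjusted p = 0.0484 with an estimated correlation). So did MHC class II (0 of 9, 1 adjusted over the list alone; mean 0.52, adjusted p = 0.0101, adjusted p = 0.123 with an estimated correlation) and macrophage and microglia markers (0 of 17, 1 adjusted over the list alone; mean 0.55, adjusted p = 2.83e-04, adjusted p = 0.184 with an estimated correlation). CD163 measured 1.77 ± 0.41 (adjusted p = 0.197), CCL2 1.26 ± 0.31 (adjusted p = 0.291) and GFAP -0.22 ± 0.41 (adjusted p = 0.995), none of which passed. The homeobox gene HOXD13 had the smallest p among lower genes, -1.62 ± 0.34 (adjusted p = 0.106), and limma called none lower. With array period as a block 10 probe sets were called, 6 among early arrays and 0 among late arrays, with 1 control; without SIV-328 the count was 20, and without the 3 samples of raised ratios it was 12, with IFI44 and PSMB9 not among them.

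The occipital lobe comparison rested on 2 control animals. In it 2 of 7366 probe sets passed, and 725 had an unadjusted p under 0.05. IFI44 was higher in the 4 SIV animals (3.47 ± 0.35, adjusted p = 0.0317) and TGM2, a transglutaminase that cross-links matrix proteins, was higher there too (3.32 ± 0.36, adjusted p = 0.0317; 2.50 to 4.51 over the alternatives). MX1 measured 3.63 ± 0.45 (adjusted p = 0.0527), IFIT1 3.72 ± 0.49 (adjusted p = 0.0546), B2M 2.75 ± 0.38 (adjusted p = 0.0632) and, among lower genes, the potassium channel subunit KCNF1 -2.83 ± 0.44 (adjusted p = 0.116), none of which passed. Both calls were lost in all 6 refits without 1 animal, which left 0 or 1 calls by limma. With the GAPDH ratio as a covariate limma called 0, as without the raised-ratio sample of control-331. With array period as a block 3 were called, and among early arrays, with 1 control, 0.

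As lists in occipital lobe, interferon-stimulated genes (1 of 31 rose; 15 adjusted over the list alone; mean 1.52, adjusted p = 2.13e-14, adjusted p = 0.215 with an estimated correlation) were higher. So were MHC class I genes (0 of 10; 6 adjusted over the list alone; mean 1.36, adjusted p = 4.84e-06, adjusted p = 0.464 with an estimated correlation). Macrophage and microglia markers (0 of 27; 2 adjusted over the list alone; mean 0.79, adjusted p = 7.52e-04, adjusted p = 0.667 with an estimated correlation) were higher as well. Chemokines, cytokines and adhesion molecules were also higher as a list (0 of 15; 1 adjusted over the list alone; mean 0.85, adjusted p = 7.52e-04, adjusted p = 0.417 with an estimated correlation). Immediate early genes, which neurons switch on with activity, were lower as a list (0 of 16; 0 adjusted over the list alone; mean -0.61, adjusted p = 7.56e-04, adjusted p = 0.531 with an estimated correlation). EGR1 measured -1.83 ± 0.82 (adjusted p = 0.510) and FOS -0.99 ± 0.38 (adjusted p = 0.476). The GAPDH ratio was lower in these SIV samples, by -1.10.

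**Figure D2:**
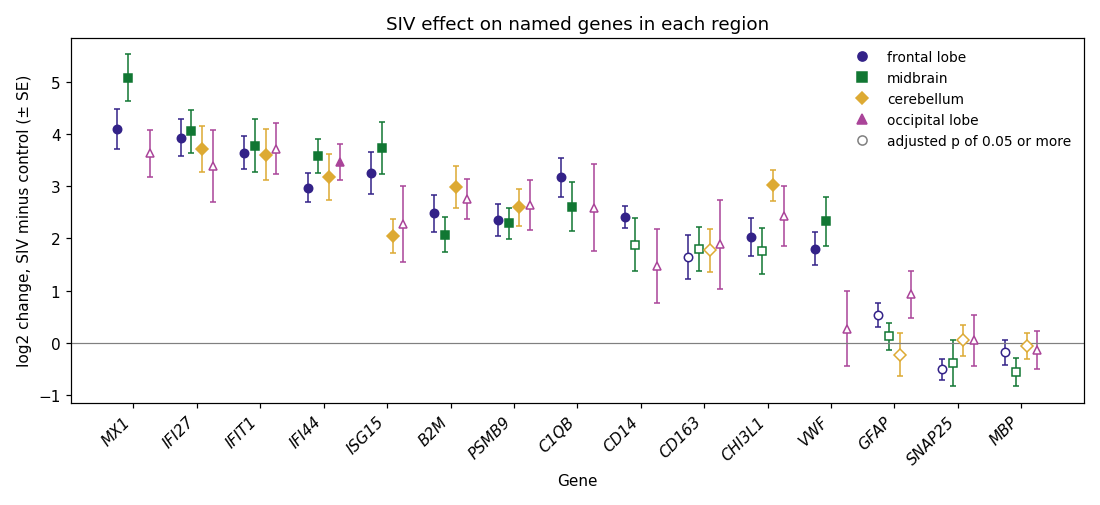
The log2 change from control to SIV animals with its SE is plotted for 15 genes in each brain region, filled where the adjusted p was under 0.05 and open otherwise; a gene too dim to be tested in a region has no point there. MX1 reaches 5.08 in midbrain, while the open points of SNAP25 and MBP lie near 0.

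Averaged over the 4 regions, with the animal as a random block (17 control and 19 SIV samples of 12 animals), the interferon genes had the smallest p. The block used 1 correlation of 0.0413 for all probe sets, so samples of an animal counted as nearly independent. Where the regions of an animal share a gene's level more strongly than that, its p is too small. IFI44 was 9.77-fold higher (3.29 ± 0.20, adjusted p = 2.30e-14), IFIT1 12.9-fold (3.69 ± 0.25, adjusted p = 4.17e-13) and MX1 15.5-fold (3.95 ± 0.31, adjusted p = 1.97e-11); IFI44 and IFIT1 in all 19 SIV samples lay above all 17 control samples. PSMB9 rose 5.48-fold (2.45 ± 0.20, adjusted p = 2.52e-11) and B2M 5.88-fold (2.56 ± 0.22, adjusted p = 1.80e-10). PSMB8 was at the floor in all 17 control samples and above it in 18 of 19 SIV samples, with a fitted log2 change of 2.59 ± 0.33 (adjusted p = 1.06e-06) that ran from 1.48 to 3.25 over the alternatives. CD163, the macrophage scavenger receptor, passed here at 3.36-fold (1.75 ± 0.29, adjusted p = 1.05e-04), higher than every control sample in 15 of 19 SIV samples.

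In this fit 324 of 9696 probe sets were called, 257 higher and 67 lower, with 1507 at an unadjusted p under 0.05. At least 1.5-fold changes numbered 243 higher and 58 lower. The called probe sets held 212 genes that rose and 59 that fell, with 16 probe sets of several symbols and 20 of none here. Of 37 interferon-stimulated genes 25 rose and 12 did not pass (29 adjusted over the list alone; mean 1.47, adjusted p = 1.85e-80, adjusted p = 2.26e-06 with an estimated correlation). Of 10 MHC class I genes 9 rose (9 adjusted over the list alone; mean 1.56, adjusted p = 4.04e-37, adjusted p = 7.94e-05 with an estimated correlation), among them TAP1 (a peptide transporter) at 3.89-fold (1.96 ± 0.24, adjusted p = 5.43e-07) and HLA-E at 2.99-fold (1.58 ± 0.19, adjusted p = 2.60e-07). Of 11 MHC class II genes 3 rose and 8 did not pass (4 adjusted over the list alone; mean 0.65, adjusted p = 5.45e-07, adjusted p = 0.0122 with an estimated correlation). Of 35 macrophage and microglia markers 12 rose and 23 did not pass (19 adjusted over the list alone; mean 0.80, adjusted p = 1.34e-18, adjusted p = 6.92e-04 with an estimated correlation). Among them were the leukocyte proteins CD53 at 2.33-fold (1.22 ± 0.20, adjusted p = 6.51e-05) and LAPTM5 at 2.59-fold (1.37 ± 0.23, adjusted p = 9.90e-05). Of 20 chemokines, cytokines and adhesion molecules 8 rose and 12 did not pass (11 higher and 1 lower adjusted over the list alone; mean 0.58, adjusted p = 8.88e-09, adjusted p = 0.00107 with an estimated correlation). They included CCL8 at 3.25-fold (1.70 ± 0.24, adjusted p = 7.68e-06) and VCAM1, the endothelial receptor for leukocytes, at 2.53-fold (1.34 ± 0.24, adjusted p = 2.69e-04). Over the alternatives, floors included, the change ran from 0.86 to 2.13 for CCL8, 0.60 to 1.72 for VCAM1 and 1.25 to 2.21 for TAP1. In the complement list C1S and C2 rose and 6 of 8 did not pass (4 adjusted over the list alone; mean 0.56, adjusted p = 1.94e-04, adjusted p = 0.0122 with an estimated correlation).

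Vascular markers rose over all regions in 5 of 18 cases (5 adjusted over the list alone; mean 0.33, adjusted p = 0.00173, adjusted p = 0.0461 with an estimated correlation), with FN1 at 2.40-fold (1.26 ± 0.16, adjusted p = 1.09e-06). Of 21 astrocyte markers 3 rose, CHI3L1, the filament protein VIM and the acute-phase inhibitor SERPINA3 (3 adjusted over the list alone; mean 0.20, adjusted p = 0.0473, adjusted p = 0.323 with an estimated correlation), whereas GFAP measured 0.34 ± 0.19 (adjusted p = 0.385). VIM rose 2.13-fold (1.09 ± 0.18, adjusted p = 1.01e-04) and SERPINA3 2.73-fold (1.45 ± 0.26, adjusted p = 3.54e-04). Immediate early genes fell as a list, with 2 of 17 lower, EGR1 and EGR4 (1 higher and 6 lower adjusted over the list alone; mean -0.29, adjusted p = 0.00477, adjusted p = 0.0909 with an estimated correlation). EGR1 and EGR4 each lost the call in 7 of 12 refits without 1 animal, with an adjusted p of up to 0.167 and 0.313. The transcription factor FOS, which another probe set represents in the list, fell by 1.07 by the probe set with the largest change (-1.07 ± 0.23, adjusted p = 0.00373); its 2 other probe sets did not pass, nor did this 1 without the samples of raised ratios. The 25 neuronal markers averaged -0.20 with 1 lower, STMN2 (1 adjusted over the list alone; adjusted p = 0.00370, adjusted p = 0.164 with an estimated correlation). The 15 glutamatergic synapse genes averaged -0.28 with 1 lower, HOMER1 (1 adjusted over the list alone; adjusted p = 0.0266, adjusted p = 0.127 with an estimated correlation). The 25 mitochondrial electron transport genes averaged -0.16 with 0 called by limma (0 adjusted over the list alone; adjusted p = 0.0316, adjusted p = 0.323 with an estimated correlation). STMN2 and HOMER1 lost their calls in 11 and 7 of 12 refits without 1 animal. SNAP25, a synaptic protein, measured -0.18 ± 0.18 (adjusted p = 0.676) and MBP, the myelin basic protein, -0.22 ± 0.14, and neither passed.

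The remaining lists did not pass over all regions. T and NK lymphocyte markers averaged 0.01 over 17 genes (adjusted p = 0.993) with 0 members called by limma. B lymphocyte and plasma cell markers averaged 0.08 over 6 genes with a median of -0.11 (adjusted p = 0.978); IGLC1, a light chain constant region, rose 2.38-fold (1.25 ± 0.28, adjusted p = 0.00511), while 1 of its 2 other probe sets measured the opposite sign. A probe set of IGHM, the heavy chain of IgM, rose 5.29-fold (2.40 ± 0.49, adjusted p = 0.00199), but another measured -0.33 ± 0.20 (adjusted p = 0.444), so the probe sets of this gene disagreed. Oligodendrocyte and myelin markers averaged 0.04 over 14 genes (adjusted p = 0.819), with 0 members called by limma. GABAergic genes averaged -0.16 over 12 (1 lower, SST; adjusted p = 0.183), and SST lost its call in 10 of 12 refits without 1 animal. Metallothioneins and heat shock proteins averaged 0.15 over 14 (1 higher, CRYAB; adjusted p = 0.326) and hypoxia and glycolysis genes 0.09 over 13 (1 higher, DDIT4; adjusted p = 0.708). CRYAB, a small heat shock protein, rose by 0.95 ± 0.18 (adjusted p = 5.09e-04), and the DDIT4 call was lost without SIV-301 or control-393, with an adjusted p of up to 0.115. Markers of cerebellar neurons averaged -0.10 over 13 genes (adjusted p = 0.357) and of forebrain cortex -0.08 over 11 (adjusted p = 0.498), with 0 members called by limma. Markers of midbrain monoaminergic neurons averaged -0.17 over 14 (adjusted p = 0.183), with 1 higher, GCH1. In the red blood cell list, too small to test as a group, the beta-globin gene HBB measured -0.042 ± 0.20 (adjusted p = 0.952) and ALAS2, an enzyme of heme synthesis, -0.48 ± 0.28 (adjusted p = 0.414).

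Among the lower genes over all regions, KRT1 fell by 1.39 (-1.39 ± 0.26, adjusted p = 6.30e-04), from -1.59 to -0.85 over the alternatives. In SIV midbrain KRT1 measured 5.04 to 5.14 in all samples but that of SIV-321. These values lie at or near the floor of 5.04, so the size depends on the floor there. PTPRS, a receptor phosphatase of axons, fell by 1.14 (-1.14 ± 0.26, adjusted p = 0.00663) and CA11, a carbonic anhydrase-related protein, by 1.41 (-1.41 ± 0.34, adjusted p = 0.0110). Without control-393 the adjusted p was 0.0802 for PTPRS and 0.110 for CA11, neither of which then passed. Leaving out control-393, control-331 or the 7 samples of raised ratios left 1 control occipital sample, which then stood for the whole control group there. Changes in calls under these refits therefore cannot be laid to RNA quality.

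**Figure D3:**
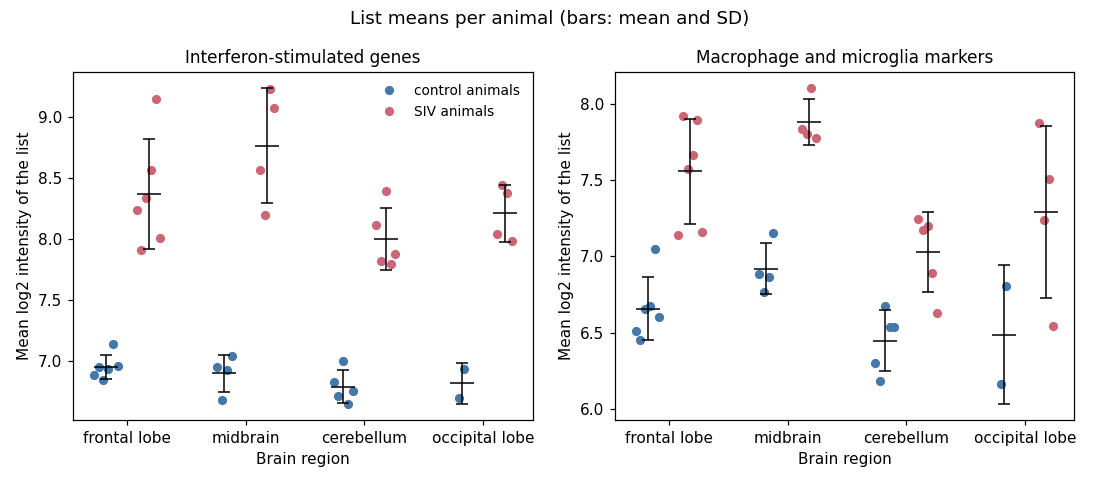
The mean log2 intensity of the interferon-stimulated gene list (left) and of the macrophage and microglia list (right) is plotted for each animal in each brain region, with bars for the mean and SD of each group. In the interferon panel every SIV point lies above every control point of all regions.

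Whether infection changed a gene by different amounts in different regions was tested directly, against frontal lobe. In midbrain 1 probe set passed, SERPINA5, a serine protease inhibitor, whose SIV effect was larger than in frontal lobe by 1.72 ± 0.26 (adjusted p = 9.72e-04); 653 probe sets had an unadjusted p under 0.05. Its log2 values in the 4 SIV midbrain samples were 7.32, 6.75, 6.86 and 6.38, with most other samples at the floor of 5.04. Values at the floor do not vary, and the SE is pooled over all groups. The SE and the p of SERPINA5 therefore do not measure the spread between animals, and the size depends on the floor. No probe set passed by limma for cerebellum or occipital lobe, where 413 and 819 had an unadjusted p under 0.05. Interferon-stimulated genes rose more in midbrain than in frontal lobe by a mean of 0.44 over 37 genes (adjusted p = 0.00270, adjusted p = 0.609 with an estimated correlation). The effect on oligodendrocyte genes was lower in midbrain by -0.53 over 14 genes (adjusted p = 0.00270, adjusted p = 0.496 with an estimated correlation), and that on astrocyte markers by -0.36 over 21 (adjusted p = 0.0226, adjusted p = 0.496 with an estimated correlation). Beside these list differences, the beta-actin log2 ratio differed between SIV and control animals by 1.52 in midbrain and -0.07 in frontal lobe. The macrophage and microglia list differed by 0.04 over 35 genes (adjusted p = 0.986). Without SIV-289 no probe set passed by limma in any of the 3 tests. Without control-298, SIV-301, SIV-330 or control-357 the count was 2, and without SIV-328 it was 5. It was 311 without control-331 and 921 without the 7 samples of raised ratios, both of which leave 1 control occipital sample.

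Across regions the direction of change was shared. Of the 86 probe sets called in frontal lobe, 82 (95.3%) had the same sign in midbrain, 77 (89.5%) in cerebellum and 80 (93.0%) in occipital lobe. The regions came from the same animals, so the chance value was taken from the 70 exchanges of animals between the groups that keep every region's group sizes. Other exchanges had medians of 58.1%, 58.1% and 61.6%, with highest values of 86.0%, 76.7% and 79.1%, and the real grouping was the highest of 70 in each region. The sign in the other region was not tested per probe set.

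Between regions of the control animals, genes of regional neuron types were among those that differed. In midbrain (n = 4) against frontal lobe (n = 6), TH, the rate-limiting enzyme of dopamine synthesis, was 6.64-fold higher (2.73 ± 0.50, adjusted p = 4.87e-04), and the neurofilament heavy chain NEFH 10.2-fold higher (3.35 ± 0.36, adjusted p = 3.21e-08). TBR1, a transcription factor of cortical glutamatergic neurons, was at the floor in all 4 midbrain samples. It was lower by a fitted change of -5.04 ± 0.36 (adjusted p = 9.84e-13), a size that depends on the floor. CAMK2A, a kinase of forebrain synapses, fell by 5.04 (-5.04 ± 0.35, adjusted p = 5.60e-13). Of 9696 probe sets 450 were called, 224 higher and 226 lower, with 1487 at an unadjusted p under 0.05. They held 189 genes higher and 177 lower. Oligodendrocyte and myelin genes were higher, 8 of 14 (10 adjusted over the list alone; mean 1.10, adjusted p = 7.81e-12, adjusted p = 0.00277 with an estimated correlation), with MBP at 2.19-fold (1.13 ± 0.25, adjusted p = 0.00336). Astrocyte markers were higher in 4 of 21 cases (6 adjusted over the list alone; mean 0.47, adjusted p = 0.00252, adjusted p = 0.0655 with an estimated correlation). Glutamatergic synapse genes were lower, 7 of 15 (7 adjusted over the list alone; mean -1.38, adjusted p = 1.48e-15, adjusted p = 7.22e-05 with an estimated correlation). Forebrain cortex markers were lower too, with 7 lower and 1 higher of 11 (8 and 1 adjusted over the list alone; mean -1.87, adjusted p = 1.37e-22, adjusted p = 9.91e-04 with an estimated correlation). GABAergic genes were lower as a list, with 4 lower and 1 higher of 12 (4 and 2 adjusted over the list alone; mean -0.64, adjusted p = 0.0240, adjusted p = 0.0769 with an estimated correlation), and so were immediate early genes, 1 of 17 (5 adjusted over the list alone; mean -0.61, adjusted p = 7.19e-04, adjusted p = 0.0590 with an estimated correlation). The midbrain monoaminergic list, to which TH belongs, did not pass (2 higher and 1 lower of 14; 5 and 3 adjusted over the list alone; mean 0.30, adjusted p = 0.229). Its member NR4A2, a transcription factor of dopamine neurons, fell by 1.26 (-1.26 ± 0.37, adjusted p = 0.0432), a call lost in all 6 refits without 1 control animal (adjusted p = 0.0512 to 0.266). With the animal as a fixed block over the 4 control animals that gave both regions, MBP no longer passed and 247 probe sets were called, and without control-298, control-332 or control-357 the count was 235, 266 or 290.

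In cerebellum (n = 5) against frontal lobe (n = 6) of control animals, ZIC1, a transcription factor of granule neurons, was 23.8-fold higher (4.57 ± 0.31, adjusted p = 1.60e-13). GABRA6, the granule-cell GABA receptor subunit, was higher by a fitted 2.91 ± 0.20 (adjusted p = 1.98e-13). With 5 of 6 frontal samples at the floor, that size depends on the floor. LCAT, the enzyme that esterifies cholesterol, was 33.9-fold higher (5.08 ± 0.54, adjusted p = 1.04e-08). NRGN, a postsynaptic calmodulin-binding protein of forebrain, was lower by a fitted -7.14 ± 0.47 (adjusted p = 7.10e-14), a size that depends on the floor, where 4 of 5 cerebellum samples lay. In all 716 probe sets were called, 365 of them higher, with 1891 at an unadjusted p under 0.05. They held 314 genes higher and 286 lower. Cerebellar neuron markers were higher, 11 of 13 (12 adjusted over the list alone; mean 2.11, adjusted p = 7.87e-33, adjusted p = 4.04e-10 with an estimated correlation). Forebrain cortex markers were lower, with 7 lower and 1 higher of 11 (8 and 1 adjusted over the list alone; mean -2.22, adjusted p = 2.52e-27, adjusted p = 5.45e-04 with an estimated correlation). Glutamatergic synapse genes were lower, with 5 lower and 1 higher of 15 (5 and 1 adjusted over the list alone; mean -1.22, adjusted p = 1.73e-08, adjusted p = 0.00788 with an estimated correlation), and GABAergic genes too, with 6 lower and 3 higher of 12 (8 and 3 adjusted over the list alone; mean -0.97, adjusted p = 4.37e-04, adjusted p = 0.0227 with an estimated correlation). Oligodendrocyte genes, 1 of 14 lower (4 adjusted over the list alone; mean -0.47, adjusted p = 0.0230, adjusted p = 0.303 with an estimated correlation), were lower as a list. Immediate early genes, 3 of 17 lower (3 adjusted over the list alone; mean -0.63, adjusted p = 0.00506, adjusted p = 0.129 with an estimated correlation), were lower too. With the animal as a fixed block over the 5 shared control animals 414 probe sets were called.

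Occipital lobe (n = 2) and frontal lobe (n = 6) of control animals are both cerebral cortex, and 2 of 9696 probe sets were called between them, with 709 at an unadjusted p under 0.05 and 0 lists past the threshold by camera. SYT2, a calcium sensor of fast synaptic release, was 6.57-fold higher in occipital lobe (2.72 ± 0.42, adjusted p = 0.00168), and SLIT1, an axon guidance protein, fell by 1.92 (-1.92 ± 0.37, adjusted p = 0.0387). The SLIT1 call was lost without control-332, control-357, control-392 or control-393, after quantile normalization, with array period as a covariate and with the animal as a fixed block. Its adjusted p reached 0.997 without control-393. SYT2 lost its call without control-393 (adjusted p = 0.168) and with the animal as a fixed block over the 2 shared animals (adjusted p = 0.993), where limma called 0 probe sets. The count was 280 without control-331 and 723 without the samples of raised ratios, both of which leave 1 occipital control.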

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

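The tests of blood and of the share of neurons for the macrophage and microglia list were chosen after the result was seen; the other tests of this part were written before theirs. A group was flagged where the gap from 1 sample to its nearest neighbour was a large share of the group's range. This held in 7 of 161 groups tested (5 of 88 for genes, 1 of 59 for list means, 1 of 14 for ratios). Chance marks about 1 group in 20 where no values tie at the floor. With all other samples at the floor any value above it is flagged, however near, as for MX1 and CHI3L1 below. A group wholly at the floor cannot be flagged. In frontal lobe, control-392 had a mean log2 value of 7.05 for macrophage and microglia markers, against 6.46 to 6.67 in the other 5 controls, and a beta-actin log2 3' to 5' ratio of 1.64, against 0.27 to 0.60. In midbrain, MX1 was 6.03 in control-357 with the other controls at the floor of 5.04, TYMP was 7.58 in SIV-301 against 9.50 to 9.82, and KRT1 was 6.28 in SIV-321 against 5.04 to 5.14. In cerebellum, CHI3L1 was 5.08 in control-393 with the others at the floor of 5.04, and B2M was 12.26 in SIV-328 against 10.05 to 10.63.

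The SIV effect in midbrain differed from that in frontal lobe, by a test of the difference itself, for SERPINA5 (1.72), interferon-stimulated genes (0.44), astrocyte markers (-0.36) and oligodendrocyte and myelin markers (-0.53). With an estimated correlation none of the 3 lists passed (adjusted p = 0.609, 0.496 and 0.496). Without SIV-289 or SIV-321 SERPINA5 fell under the filter on dim probe sets and was not tested. Its call also rests on a pooled spread that samples at the floor lower. The raised beta-actin ratio of SIV midbrain, 1.52 above control against -0.07 in frontal lobe, goes with these differences, and its part in those of the lists was not tested. For the number of probe sets called as different between regions, chance cannot be excluded: 13 of 70 exchanges of animals, the real one among them, gave a count as large as the real 1, and the highest other was 2.

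Calls in midbrain were weighed against RNA degradation, because the beta-actin ratio was raised in SIV midbrain. If degradation had made them, the same probe sets would show no SIV effect in frontal lobe, where the ratios of both groups were alike. The 68 higher probe sets, with a median change of 2.30 in midbrain, had a median of 1.47 in frontal lobe, where 65 of 68 rose and random sets of that size gave -0.10 to 0.10, which argues against degradation and is in line with an effect of infection in both regions. The 18 lower probe sets, at -1.89 in midbrain, had a median of -0.36 in frontal lobe, outside the random range of -0.18 to 0.19 and 19.1% of the midbrain value, so part of the lower calls may still be due to degradation.

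The higher macrophage and microglia list (mean 0.80 ± 0.10 SE over 35 genes, all regions) was weighed against tissue composition. Blood left in the tissue would raise beta-globin by as much. Averaged over the regions HBB measured -0.042 ± 0.20 (SE of the fit), which argues against blood for this average only. Its SIV effect differed from that in frontal lobe by -0.94 in midbrain, -0.29 in cerebellum and -0.94 in occipital lobe. None of these differences passed, and blood was not weighed within single regions. A lower share of neurons would raise markers of other brain cells alike. Averaged over all regions, the oligodendrocyte list measured only 0.042 ± 0.061 over 14 genes and the astrocyte list 0.20 ± 0.16 over 21. The SEs of these lists and of the macrophage list are over genes, so they do not measure the spread between animals. The oligodendrocyte effect in midbrain also differed from that in frontal lobe by -0.53. A shift in the share of neurons, above all within single regions, is therefore not ruled out. More macrophages or microglia, or a higher expression per cell, stay open, and these data do not separate them.

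The record of 1 midbrain array, labelled as SIV-289, names SIV-301. Over 500 probe sets the sample's deviations correlated at 0.01 with the other regions of SIV-289 and at -0.12 with those of SIV-301, a margin of 0.13 with an SD of 0.157 over the other samples. It correlated best, at 0.145, with SIV-330. The test did not decide which number is right. If the record is right, SIV midbrain holds 3 animals, SIV-301 among them 2 times; without this array 48 probe sets in place of 86 were called in midbrain, and without every sample of SIV-289 0 by limma in place of 1 for the difference between regions, with SERPINA5 then not tested.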

How the results depend on the processing

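No named gene or list that passed changed direction under an alternative run. Among values of named genes that passed, 3416 kept the call and 631 lost it; among those that did not pass, 13891 stayed so, 226 passed and 221 moved without passing. For lists that passed, 212 values kept the call and 44 lost it; of the others 437 stayed so, 25 passed and 38 moved. Unless the construction shows it (fewer samples, fewer probe sets or an assumed variance), the cause was not tested. Deposited and quantile-normalized values gave counts within 1.5 times of each other in every SIV comparison.

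In frontal lobe 86 calls became 47 with early arrays alone, 0 with late arrays alone, 181 with array weights and 161 with all 24 arrays and a random replicate block, and 66 to 117 when each animal was left out. In midbrain 86 became 137 with the floor at the 40th percentile, 42 with no filter, 0 within either period alone (1 animal in a group, so these say nothing on period), 51 with the GAPDH covariate, 35 with the beta-actin covariate, 138 with trend and robust variance, 135 in the 8-group fit with its random replicate block and 37 without raised-ratio samples (leaving out animals: 44 to 116). In cerebellum 12 became 6 with early arrays, 0 with late arrays, 28 with array weights and 34 in the 8-group fit (10 to 20). In occipital lobe 2 became 14 with the floor at the 40th percentile, 7 with no filter, 10 with the filter at the 75th percentile, 12 with trend and robust variance, 57 in the 8-group fit, and 0 with early arrays, the GAPDH covariate, array weights or without the raised-ratio sample (0 to 1); late arrays alone, 1 control and 1 SIV animal, were not run.

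Over all regions 324 became 525 without raised-ratio samples, 385 with no replicate block, and 216 to 616 when animals were left out. The single call for a difference between regions became 2 with the period covariate, 921 without raised-ratio samples, 1 with no replicate block and 0 to 311 by animal. With a fixed replicate block of shared animals the contrasts between control regions gave 247 in place of 450 for midbrain (235 to 397 by animal), 414 in place of 716 for cerebellum (509 to 705) and 0 in place of 2 for occipital lobe (1 to 280), where quantile normalization gave 1, the period covariate 1 and the fit without raised-ratio samples 723. Refits that left 1 sample in a group assume that it varies like the others. Those without raised-ratio samples, control-331 or control-393 are among them, as each left 1 control occipital sample. With no replicate block these contrasts gave 426, 656 and 2; the block changed no other call by over 1.5 times. No paired analysis was possible for SIV against control because the groups share no animal.

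With an estimated correlation the lists past the threshold numbered 6 in place of 11 in frontal lobe, 0 in place of 11 in midbrain, 3 in place of 5 in cerebellum, 0 in place of 5 in occipital lobe, 7 in place of 12 over all regions and 3 in place of 6 between midbrain and frontal lobe of controls; without the raised-ratio sample 1 list passed in occipital lobe. The ratio difference in midbrain was 1.52 with beta-actin against 0.88 with GAPDH, and in occipital lobe 0.35 against -1.10, the opposite sign. The correlation of repeat arrays was 0.914 with the floor at the 40th percentile against 0.876. Background itself was not measured here. The floor, at the 20th percentile of all values by choice, held 12.2% to 27.2% of the values of an array, and what lay under it was not told apart. Fold changes from the floor within a region are lower bounds.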

Other observations

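Both tests in this part for the level of a list in each animal, and the tests that regroup samples freely, were written before their results were seen; the comparison with groupings that part every pair had no prediction written beforehand. Each SIV animal's list level was followed across its regions, to see whether it is a property of the animal. For interferon-stimulated genes, means centred within each region ran from -0.34 in SIV-301 to 0.32 in SIV-328 (37 genes, 19 samples of 6 animals; permutation p = 0.0458, Benjamini-Hochberg value 0.0917 over both lists). For macrophage and microglia markers they ran from -0.57 in SIV-330 to 0.25 in SIV-301 (35 genes; permutation p = 0.125). Animal SIV-301 thus had the lowest mean of the interferon list and the highest of the macrophage list, an order that was not tested.

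Regrouping the samples asked how often chance gives counts as high as the real ones, with no adjustment over these tests. The real grouping gave the highest count of probe sets, 1 of the groupings reaching it, in frontal lobe (86 against 1 as the highest other, 100 groupings), midbrain (86 against 4, 35 groupings), cerebellum (12 against 3, 100 groupings), and over all regions (324 against 119, 70 groupings). Control regions share animals, so there the real grouping was compared with those that part every pair as it does. Between cerebellum and frontal lobe the real grouping was the highest of 32 (716 against 421), and the 68 groupings of the other kind drawn gave at most 358. The 32 include the swap of both regions in every pair, which mirrors the real grouping but for the place of control-392. With such mirrors counted as the same, too few groupings remain for a share under 1 in 20, so chance was not excluded there. Between midbrain and frontal lobe the 16 groupings are too few for a share under 1 in 20 (450 against 25); the 84 of the other kind gave at most 65. For lists past the threshold in midbrain, the real grouping was the highest of 35 at the preset correlation (11 against 9). That share, 1 of 35, is under 1 in 20 but is the smallest that 35 groupings can give. With an estimated correlation 0 lists were left, and the real grouping went partly with array period, so chance is not firmly excluded. Chance was not excluded for lists in frontal lobe (9 of 100 groupings as high as the real 11, highest other 16) or cerebellum (5 of 100 as high as the real 5, highest other 8). For occipital lobe, with 2 controls, there are too few groupings to tell.

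The instrument records disagreed with the labels for 3 samples. The cerebellum array of control-393 was recorded as cortex, the midbrain array of SIV-289 carried the number of another animal, and the frontal lobe arrays of control-392 had a sample type of cerebellum beside a description of frontal lobe. Cerebellar neuron markers averaged 8.18 in the frontal lobe of control-392, against 7.81 to 8.05 in that of the other controls and 9.96 to 10.28 in control cerebellum, where control-393 had 10.28. Forebrain cortex markers averaged 8.64 there, against 8.84 to 9.66 and 6.74 to 7.14. By both lists the frontal lobe sample of control-392 lay nearer to frontal lobe, and the cerebellum sample of control-393 within the cerebellum samples.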
